A study of Homo sapiens with 36 samples.

How the data were processed

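The starting material was the deposited featureCounts tables of read counts per feature, 1 table per library, made by the authors from Illumina libraries sequenced on a NovaSeq. Per the labels, STAR 2.7.3a, Cufflinks 2.2.1 and featureCounts 2.0.0 were used on hg38, without their parameters. The unit, counts, was checked against the files: all values were whole numbers. The 3 data sets were cytoplasm total RNA, chromatin total RNA and cytoplasm polyA RNA, each with 12 libraries in 4 groups of 3, or 36 in all. Totals ran from 59.5 to 122.6 M counts in the cytoplasm total RNA, from 50.3 to 139.0 M in the chromatin and from 25.9 to 33.1 M in the polyA set.

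The total RNA tables hold 59607 features, of which 58174 are Ensembl genes and 1433 are assembled loci that carry only a locus number. The polyA tables hold 60095 features: 51223 Ensembl genes, the 1433 assembled loci and 7439 regions named as enhancer RNA (eRNA). Gene classes, symbols and positions came from GENCODE 29 on hg38 (57836 of the total RNA features and 50916 of the polyA features found there) and from a newer table of names. The assembled loci and eRNA regions have neither coordinates nor symbols in the files. Where genes tested, passed or shared are counted over a whole data set, all features are meant, assembled loci and eRNA regions included. Whether the loci were assembled from these same libraries is not given. If they were, neither the direction in which they moved nor the fraction in which they were higher is independent evidence.

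The polyA tables lack 6453 of 19762 protein-coding genes. Among the genes with coding transcript models only, 99.2% were missing, and among genes with a non-coding model 99.1% were present. PolyA values for protein-coding genes therefore appear to cover their non-coding models only, and were not compared in level with the total RNA values. Features nested in another gene on the same strand appear to share its reads: the containing gene's count was at least as high in 182 of 182 pairs on the same strand and in 7 of 15 on opposite strands, which sharing would give but does not prove. Genes named for their size that overlap another gene's exons on the same strand are marked as sharing reads, in that sense, beside their values or here: FAM174B with AC091544.6, FBXL8 with AC074143.1, ANG with AL163636.2 and RNASE4, RGMA with YBX2P2, CYP1B1 with RMDN2-AS1, GGT1 with SNRPD3, AC004754.1 with ARHGDIG and FAM234A, NIPAL2 with RNU6-914P, NABP1 with RF02271, LRP1B with AC078882.1 and RF02271, MIR4680 with PDCD4 and SNORD95 with RACK1.

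Each data set was scaled by TMM, filtered with filterByExpr (min.count 10) and fitted in edgeR 4.0.16 with robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment and a threshold of adjusted p < 0.05. Scaling factors lay between 0.964 and 1.092. The biological coefficient of variation was 6.6% in the cytoplasm total RNA, 6.5% in the chromatin and 6.1% in the polyA set. Each of the 4 comparisons within a data set was tested in all 3: auxin in DIS3-AID cells, auxin in control cells, DIS3-AID against control cells without auxin, and the auxin effect in DIS3-AID minus that in control cells. The 3 comparisons across data sets were chromatin against cytoplasm in untreated control cells, the chromatin minus the cytoplasm response of DIS3-AID cells to auxin, and the polyA minus the total RNA response in the cytoplasm. DESeq2 1.42.0 was run as the other tool. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15.

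The labels call the cytoplasm triplicates technical, so p-values measure only the spread between these samples. Chi-square values per degree of freedom between replicates of 1 group ran from 5.51 to 40.89 in the cytoplasm total RNA, from 4.7 to 23.77 in the chromatin and from 2.61 to 11.91 in the polyA set, where counting alone gives about 1. No 2 libraries were duplicates. Whether libraries with the same number belong together was checked by correlating their deviations from the group means. The condition of r > 0.1 in every pair was met for auxin in control cytoplasm (0.182 to 0.398 over 3 pairs) and for the polyA minus total RNA response (0.315 to 0.538 over 6 pairs), and the results give a count with the replicate number as a block for these. Elsewhere the block is only 1 of the alternatives.

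The 29 gene lists were fixed before the data were examined. They were exosome core and catalytic subunits, exosome cofactors and nuclear decay factors, non-coding snoRNA host genes, box C/D snoRNAs, box H/ACA snoRNAs, scaRNAs, spliceosomal snRNAs, structured Pol III and other small RNAs, replication-dependent histones, divergent transcripts, antisense lncRNAs, LINC genes, pri-miRNA host genes, nuclear-retained lncRNAs, immediate-early genes, AHR targets, p53 targets, integrated stress and unfolded protein response (ISR/UPR) genes, heat shock genes, ribosomal protein genes, ribosome biogenesis factors, KRAB-type zinc finger genes, S phase genes, G2/M genes, mitochondrially encoded mRNAs, abundant cytoplasmic mRNAs, colon epithelial markers, fibroblast markers and blood cell markers. Lists were tested with camera (fixed correlation 0.01, adjusted over the lists of each comparison), again with an estimated correlation, and with fry. Lists with fewer than 3 tested members were counted and not tested. The list named KRAB-type zinc finger genes took its members by a symbol of ZNF and a number alone. No KRAB domain was checked, so it is called the ZNF-symbol list below.

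The rule for naming genes was also fixed before the data were examined. For auxin in DIS3-AID cells it took the 8 largest protein-coding rises, the 8 largest non-coding rises and the 8 largest falls with a mean of at least 1 CPM and non-overlapping replicates, and for the other comparisons 5 rises and 5 falls. From each list it took the 3 members with the smallest p past the threshold, or else the 2 with the highest mean. Members named outside this rule, where 5 or fewer of a list moved in 1 direction, were chosen after their values were seen. For genes with a group near 0 counts the ratio is given with a 95% interval, and these intervals and floors cover counting error only.

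The tests were tested on simulated data in which 200 genes were changed at a known fold. For auxin in DIS3-AID cells, 60 to 66% of 1.5-fold changes, 80.5 to 86% of 2-fold changes and 93 to 96% of 4-fold changes were recovered over the 3 data sets. For the difference of 2 responses the same figures were 44.5 to 52%, 57.5 to 67% and 83 to 92%. False calls made up 3.6 to 9.6% of the calls, so their share can exceed the 5% the threshold allows. As many simulated genes were raised as lowered, whereas in DIS3-AID cytoplasm total RNA 3407 features rose and 21 fell by at least 2-fold after auxin. These rates therefore need not hold where changes are so numerous and one-sided.

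Alternatives planned before the data were examined were RLE scaling, library sizes alone, small RNA, rRNA and mitochondrial genes left out, no expression filter, min.count 50, a test against a 1.5-fold change, the replicate number as a block, DESeq2, only the groups of the comparison, and each library left out in turn. Leaving out the assembled loci and eRNA regions, and leaving out features that overlap another gene's exons on the same strand, were added after the first results had been seen.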

Results

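RNA was compared in HCT116 cells, a human colon carcinoma line, before and after 1 h of auxin meant to remove DIS3, a catalytic ribonuclease of the RNA exosome. The control line carried TIR1, the plant receptor through which auxin marks tagged proteins for degradation. The DIS3-AID line was a CRISPR clone in which DIS3 bears the auxin-inducible degron (AID). Both were left untreated or given 500 uM auxin, and RNA was taken from the cytoplasm (total and polyA-selected) and from chromatin, the fraction that holds nascent and retained transcripts. Each of the 3 data sets had 12 libraries, 3 per group. Between 31105 and 33617 features had a count in each cytoplasm total RNA library, 32636 to 35831 in chromatin and 23668 to 26562 in polyA RNA. Levels (CPM) are counts scaled to library size adjusted by the TMM factor, as mean ± SD (n = 3). They therefore depend on that scaling, as the log2 ratios given for changes do. Positions are on hg38.

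DIS3 itself (ENSG00000083520.14, chromosome 13, 72752169 to 72782096, minus strand) was lower in the DIS3-AID clone than in the control line before any auxin. In the cytoplasm total RNA it stood at 90.49 ± 2.58 CPM in untreated control cells and 50.09 ± 2.64 CPM in untreated DIS3-AID cells (SD, n = 3; log2 difference -0.85 ± 0.05 SE, adjusted p = 2.38e-09). The difference was -0.70 in chromatin (adjusted p = 4.23e-06), from 54.74 ± 1.1 to 33.71 ± 3.54 CPM, and -0.68 in polyA RNA (adjusted p = 0.00068), from 6.94 ± 1.27 to 4.34 ± 0.29 CPM. After auxin the DIS3-AID cells had 45.8 ± 0.94 CPM in the cytoplasm (log2 -0.13, adjusted p = 0.0637), 33.88 ± 3.3 CPM in chromatin (0.01, 0.978) and 4.93 ± 0.39 CPM in polyA RNA (0.18, 0.452). Control cells given auxin had 93.03 ± 3.21 CPM in the cytoplasm (0.04, adjusted p = 0.95). PolyA values of DIS3, as of other protein-coding genes, appear to cover its non-coding models only. The degron acts on the protein, which no library measured, so these levels do not show how far DIS3 was depleted.

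To see what had accumulated after 1 h of targeting DIS3, the cytoplasm total RNA of DIS3-AID cells was compared with and without auxin. Non-coding transcripts that are normally scarce there rose many-fold within the hour. SKAP1-AS1, an antisense lncRNA (ENSG00000263787.1, chromosome 17, 48185938 to 48204529, plus strand), rose from 0.922 ± 0.0868 to 19.5 ± 1.64 CPM (SD, n = 3; log2 change 4.40 ± 0.10 SE, adjusted p = 7.06e-16). Its levels in control cells were 0.576 ± 0.0272 CPM without and 0.533 ± 0.0778 CPM with auxin. MIR378D2HG, the host transcript of a microRNA (chromosome 8, 93915734 to 93916682, minus strand), rose from 4.37 ± 0.175 to 62.1 ± 1.42 CPM (log2 3.83 ± 0.08 SE, adjusted p = 1.78e-16), with 2.9 ± 0.374 and 3.19 ± 0.113 CPM in control cells. The other large non-coding rises were ZBTB20-AS5 (4.12), AL390961.3 (3.92), the pseudogene SELENOOLP (3.87), AC005808.1 (3.78), AC002378.1 (3.73) and MIR378D2 (3.71). Of these, AL390961.3 shares reads with SELENOOLP, and MIR378D2 with its host gene.

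**Figure D1:**
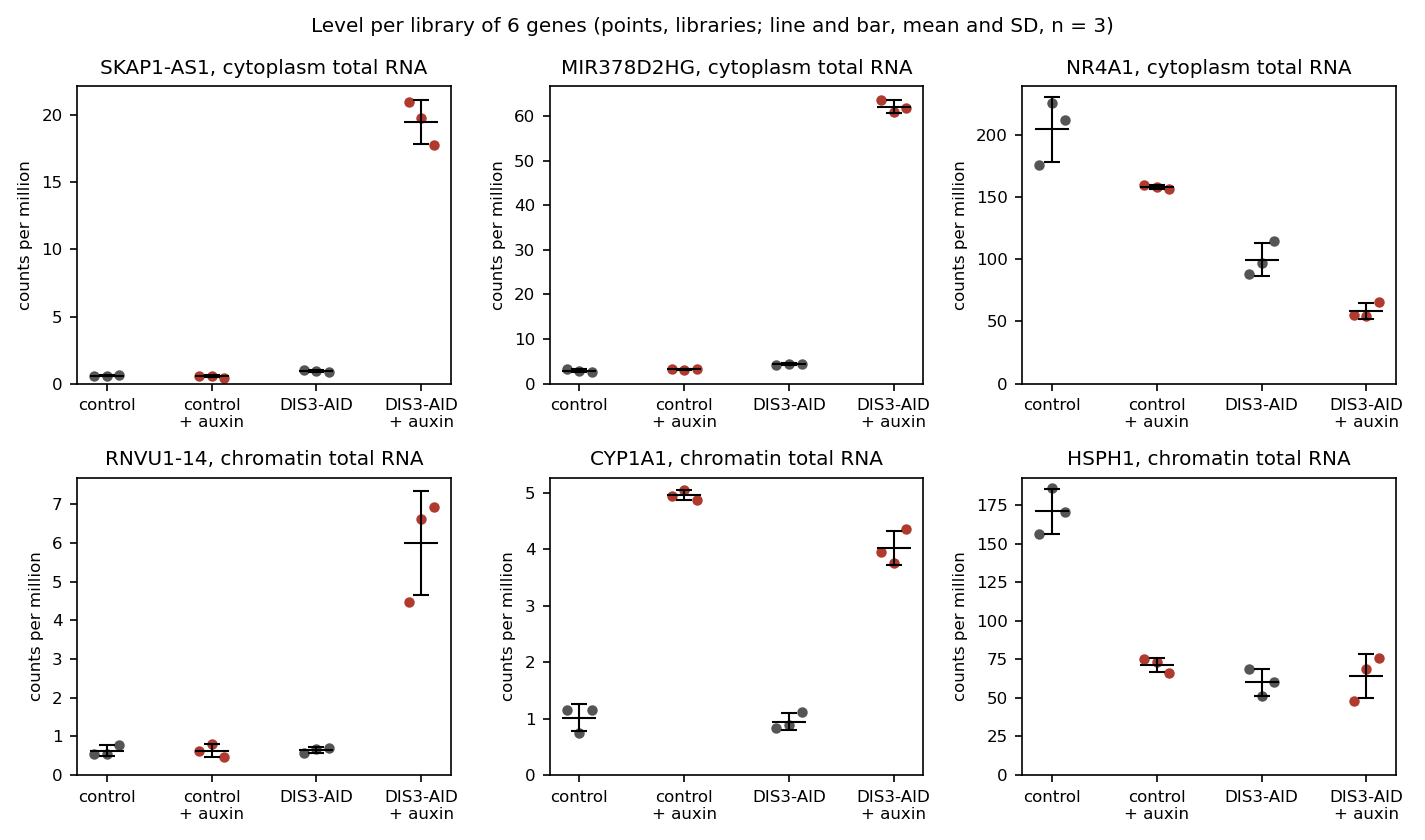
Levels in single libraries of SKAP1-AS1, MIR378D2HG and NR4A1 in the cytoplasm total RNA and of RNVU1-14, CYP1A1 and HSPH1 in chromatin. Bars give the mean and SD of n = 3 libraries.

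Divergent transcripts, which start at the promoter of a neighbouring gene and run the other way, moved most uniformly among the large lists. In this list 363 of 441 tested members rose (369 adjusted over the list alone), with a median log2 change of 1.41 and camera adjusted p = 9.13e-29 (adjusted p = 3.96e-06 with an estimated correlation). ERRFI1-DT rose from 6.17 ± 0.409 to 55.6 ± 2.44 CPM (SD, n = 3; 5.73 and 5.77 CPM in control cells), MTUS1-DT from 3.72 to 30.1 CPM and RBM12B-DT from 2.15 to 13.1 CPM. Antisense lncRNAs rose in 558 of 862 cases (582 adjusted over the list alone; median 0.82, adjusted p = 1.27e-14, and adjusted p = 0.000279 with an estimated correlation), among them ARHGAP29-AS1 (4.12 ± 0.447 to 46.2 ± 0.572 CPM) and MSRB3-AS1 (7.9 ± 0.78 to 80.5 ± 2.78 CPM). H1-10-AS1 was the only antisense member that fell (-0.32). LINC genes, the intergenic lncRNAs, had 237 rises and 5 falls among 482 (248 and 7 adjusted over the list alone; median 0.50, adjusted p = 2.55e-06, and 0.0117 with an estimated correlation), led by LINC02939 (3.46), LINC00880 (2.97) and LINC02901 (2.17). The 5 that fell were LINC02019 (-0.78), LINC00659 (-0.38), LINC02035 (-0.36), CHASERR (-0.18) and LINC01963 (-0.16). Host genes of microRNAs rose in 24 of 39 cases (24 adjusted over the list alone; median 0.59, adjusted p = 9.5e-05, and 0.0109 with an estimated correlation), with MIR5689HG at 2.62 and MIR181A2HG at 2.0.

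Counts of small nuclear and nucleolar RNAs rose in the same libraries. Spliceosomal snRNAs, mostly variant U1 genes, rose in 36 of 39 cases (37 adjusted over the list alone; median 2.21, adjusted p = 1.39e-32, and 0.0234 with an estimated correlation). RNVU1-22 went from 4.23 ± 0.263 to 34.7 ± 3.04 CPM (SD, n = 3), with log2 changes of 2.72 for RNVU1-19 and 2.64 for RNVU1-27. These genes belong to multicopy families, as do the U3 genes, and how reads of near-identical copies were counted is not given. The share of counts of the whole snRNA class was 4.47 times as high. Box H/ACA snoRNAs, guides of pseudouridylation, rose in 61 of 102 cases (61 adjusted over the list alone; median 0.94, adjusted p = 6.92e-09, and 0.0117 with an estimated correlation), with SNORA66 at 3.33, SNORA9 at 2.84 and SNORA44 at 2.36. Box C/D snoRNAs, guides of ribose methylation, rose in 50 of 124 cases and fell in 3 (51 and 4 adjusted over the list alone; median 0.33, adjusted p = 6.9e-05, but adjusted p = 0.161 with an estimated correlation). SNORD45A (2.93), SNORD43 (2.39) and SNORD3B-2 (2.35; 8.23 ± 0.681 to 42 ± 3.46 CPM) rose, while SNORD21 (-0.59), SNORD22 (-0.52) and SNORD49B (-0.16) fell. Of the snoRNAs named as rising, SNORA9 shares reads with SNHG15, SNORA44 with SNHG12, SNORD45A with RABGGTB and SNORD43 with RPL3. Their counts may therefore hold reads of these genes. Among scaRNAs of the Cajal body 9 of 18 rose (10 adjusted over the list alone), including SCARNA18 (2.48), SCARNA1 (1.66) and SCARNA7 (1.18), though the list did not pass (adjusted p = 0.25).

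Host genes of snoRNAs and nuclear-retained lncRNAs also rose. SNHG3, which shares reads with RCC1 and SNORA73A, went from 79.5 ± 1.54 to 165 ± 3.11 CPM (SD, n = 3). SNHG4, which shares reads with MATR3, went from 58.5 to 121 CPM and SNHG26 from 12.8 to 31.2 CPM. In that list 17 of 30 rose and SNHG32 fell (-0.16), or 18 and 1 adjusted over the list alone (median 0.43, adjusted p = 5.51e-05, but adjusted p = 0.161 with an estimated correlation). LINC-PINT rose from 33.3 ± 2.91 to 115 ± 0.235 CPM (1.79; 1.66 at its second feature) and NEAT1, the scaffold of paraspeckles, from 32.4 to 53 CPM (0.71). Together 7 of 13 retained lncRNAs rose (7 adjusted over the list alone; median 0.20, adjusted p = 0.0109, but adjusted p = 0.241 with an estimated correlation). The shares of all counts moved with them: snRNAs went from 0.00981 to 0.0438%, snoRNAs from 0.0341 to 0.0871% and assembled loci from 0.242 ± 0.0046 to 0.738 ± 0.018% (SD, n = 3), each with exact p = 0.1, the smallest possible with 3 against 3.

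Among protein-coding genes 399 of 14326 rose by at least 2-fold. DLGAP1, a postsynaptic scaffold (chromosome 18, 3496032 to 4455335, minus strand), went from 9.18 ± 0.681 to 81.5 ± 2.73 CPM (SD, n = 3; log2 3.15 ± 0.10 SE, adjusted p = 2.05e-13), against 6.13 ± 0.172 and 7.21 ± 1.54 CPM in control cells. MYO16, an unconventional myosin, rose from 1.47 ± 0.0423 to 15.7 ± 0.982 CPM and the hair keratin KRT86 from 1.62 to 15.9 CPM. The others were HIGD2B (3.42), CHCT1 (3.28), IGBP1C (3.24), PXT1 (3.22) and SPAG6 of the sperm flagellum (3.07), and IGBP1C shares reads with TEX14.

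Immediate-early genes, switched on within minutes of a stimulus, were lower after auxin. The nuclear receptor NR4A1 (chromosome 12, 52022832 to 52059507, plus strand) fell from 99.8 ± 13.5 to 58.4 ± 6.52 CPM (SD, n = 3; log2 -0.77 ± 0.11 SE, adjusted p = 5.08e-05), with 205 ± 26 and 158 ± 1.67 CPM in control cells. NR4A3 (-1.08), the zinc finger factor EGR3 (-1.02), the repressor BHLHE40 (-0.93), the kinase NUAK2 (-0.85), the stress cytokine GDF15 (-0.83), CCN2 (-0.83) and the receptor GPR37 (-0.79) were the other largest falls. EGR3 and NR4A3 had 26.1 and 9.81 CPM in untreated control cells and 18.4 and 7.1 CPM after auxin. In the list 33 of 47 fell (34 adjusted over the list alone; median -0.35, adjusted p = 2.55e-06, but adjusted p = 0.136 with an estimated correlation), with DUSP6, a phosphatase of ERK, at 172 ± 12.5 and 111 ± 3.32 CPM, JUNB at -0.63 and NFKBIA at -0.43. ISR/UPR genes fell in 17 of 27 cases (17 adjusted over the list alone; median -0.20, adjusted p = 0.00244, and 0.0234 with an estimated correlation), among them the ER chaperone CALR (256 ± 19.5 to 184 ± 16.3 CPM), PDIA4 (-0.41) and SESN2 (-0.35). Targets of p53 fell in 10 of 32 cases (10 adjusted over the list alone; median -0.17, adjusted p = 0.00267, but adjusted p = 0.161 with an estimated correlation), with CDKN1A, the CDK inhibitor p21, from 173 ± 13.1 to 136 ± 2.4 CPM and TNFRSF10B at -0.30.

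Smaller falls, mostly of about 0.1 to 0.3, were counted in further lists. Protein-coding genes as a class had a median of -0.10, with 20% of them lower. The camera test compares a list with all other features, among them the non-coding rises. A list near the protein-coding median can therefore pass as lower without falling more than other protein-coding genes. Ribosomal protein genes fell in 35 of 80 cases (54 adjusted over the list alone; median -0.14, adjusted p = 0.000326, but adjusted p = 0.542 with an estimated correlation), such as RPL38 (-0.33) and RPL36 (-0.22), while the muscle paralogue RPL3L rose (2.58). Replication-dependent histones fell in 24 of 57 cases (28 adjusted over the list alone; median -0.14, adjusted p = 0.00279, but adjusted p = 0.462 with an estimated correlation), including H2BC21 (-0.28) and H2AC6 (-0.26), and only H2BC6 rose (1.63). In G2/M genes 10 of 22 fell (10 adjusted over the list alone; adjusted p = 0.0142, but adjusted p = 0.512 with an estimated correlation), with MKI67 at -0.28, AURKB at -0.19 and UBE2C at -0.18. S phase genes that fell were MCM5 and MCM7 (both -0.15), CDC6 (-0.14), RRM2 (-0.13) and UNG (-0.12; list adjusted p = 0.0418, 0.389 with an estimated correlation and 0.0935 with library sizes alone). Among ribosome biogenesis factors NOP58, host of snoRNAs, rose (0.45) and NOC2L (-0.22), NCL (-0.17), NPM1 (-0.16) and NOP56 (-0.12) fell (adjusted p = 0.0308, 0.502 with an estimated correlation and 0.0935 with library sizes alone). The ZNF-symbol list of zinc finger genes had 24 rises and 37 falls among 362 (21 and 20 adjusted over the list alone; adjusted p = 0.00942, but adjusted p = 0.389 with an estimated correlation), with ZNF572 (1.83), ZNF594 (0.96) and ZNF143 (0.71) rising.

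The remaining lists did not pass as lists. Abundant cytoplasmic mRNAs (adjusted p = 0.0535) included falls of GAPDH (3270 to 2910 CPM), ALDOA (-0.18) and TUBA1B (-0.15), and colon epithelial markers (0.057) falls of CLDN4 (-0.46), EPCAM (-0.40) and CDH1 (-0.38). Heat shock genes (0.0816) fell in 4 of 9 cases, HSPB1 (-0.24), BAG3 (-0.19), DNAJB1 (-0.18) and HSPH1 (-0.17). In the AHR targets (0.622), induced by the aryl hydrocarbon receptor, CYP1A1 (1.46), CYP1B1 (0.40) and TIPARP (0.34) rose and SLC7A5 fell (-0.29). Exosome core subunits (0.269) had a rise of EXOSC6 (0.26) and a fall of EXOSC1 (-0.18), and exosome cofactors (0.0783) a rise of ZFC3H1 (0.21) and falls of TENT4B (-0.17), RBM7 (-0.17) and SRRT (-0.14). Structured Pol III RNAs (0.629), whose median of -0.07 and mean of 0.08 differ in sign, had rises of BCYRN1 (0.72) and VTRNA1-3 (0.56). Mitochondrially encoded mRNAs had a median of -0.44 (0.166), with MT-ND4 at 4240 and 3260 CPM. Too few members were tested for fibroblast markers (2, COL1A1 at -0.20) and blood cell markers (1, CD79A at -0.44 with adjusted p = 0.391).

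Of 23027 features tested with edgeR in this comparison, assembled loci included, 7894 passed adjusted p < 0.05, 4854 higher and 3040 lower. By at least 2-fold, 3407 rose and 21 fell. By class, lncRNAs had 2164 rises and 59 falls among 4430 (median 0.54, quartiles 0.04 and 1.61), snRNAs 49 rises among 76, snoRNAs 124 rises and 3 falls among 262, and pseudogenes 205 rises and 45 falls among 1602. Assembled loci rose in 1122 of 1433 cases (median 2.62), a direction that is not independent evidence if they were assembled from these libraries. Protein-coding genes had 1043 rises and 2862 falls among 14326 and a median of -0.10, which became 0.00 when scaling used library sizes alone. That scaling moved the median of all features from -0.051 to 0.049 and the calls to 5576 higher and 681 lower, so the small falls rest on the scaling while the large non-coding rises do not.

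**Figure D2:**
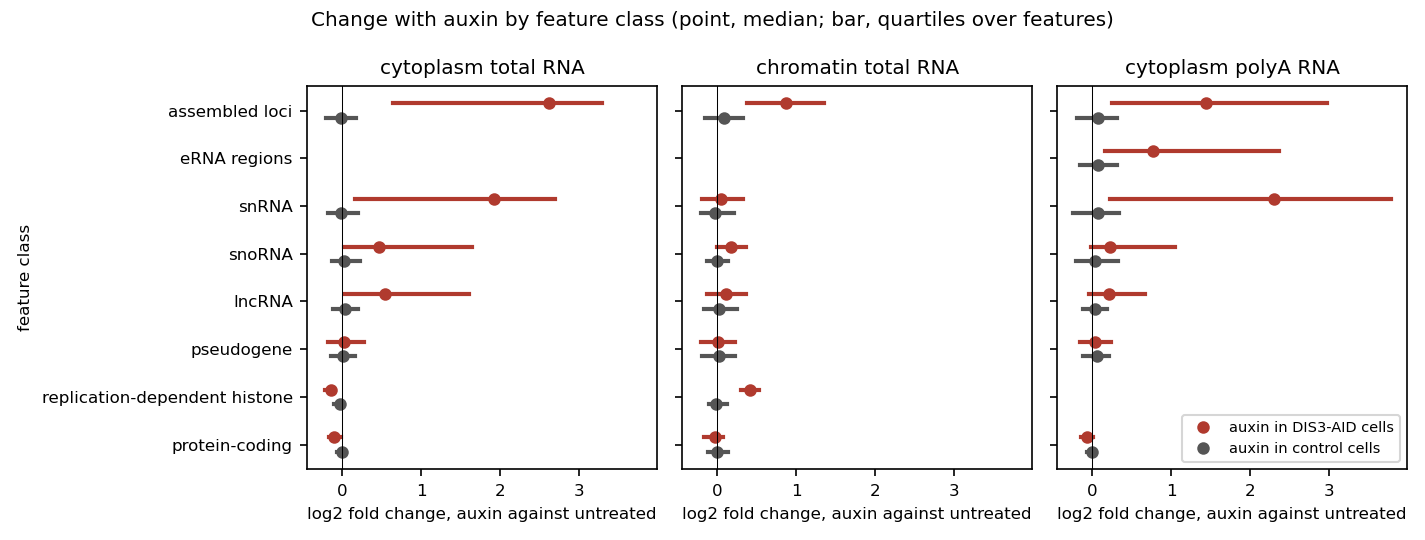
Median log2 change after auxin with quartiles for each gene class, in DIS3-AID and control cells and in the 3 data sets.

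Control cells given the same auxin served to see the response to auxin itself. Only 11 of 23027 genes passed in their cytoplasm total RNA (1413 at unadjusted p < 0.05), and 62 passed with the replicate number as a block, the setting the pairing check points to. TIPARP, an AHR target, rose from 132 ± 1.18 to 175 ± 15 CPM (SD, n = 3; log2 0.41, adjusted p = 0.0333), with ARRDC3 (0.59), MIR181A1HG (0.81) and 2 assembled loci. The falls were AC093249.2 (-0.62), HJV (-0.60), AC007952.4 (-0.57), SNORD3B-2 (-0.51), NABP1 (-0.49, adjusted p = 0.00329) and ZC3HAV1L (-0.33, adjusted p = 0.0346). AC007952.4, which shares reads with SNORD3D, went the other way in DIS3-AID cells, from 9.54 to 52.4 CPM. AHR targets passed camera (adjusted p = 2.84e-05, but adjusted p = 0.0818 with an estimated correlation), and 7 more lists passed without keeping the call with an estimated correlation. DESeq2 gave 75 genes, so the count itself is loosely determined.

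Tested directly, the auxin effect in DIS3-AID cells minus that in control cells passed in 4459 genes of the cytoplasm total RNA (3696 higher, 763 lower). SKAP1-AS1 stood at 4.49, AL390961.3 at 4.40, SELENOOLP at 4.33, ZBTB20-AS5 at 4.30 and AC005808.1 at 3.93. Lowest were RPL17P6 (-0.90), SPARC (-0.86), CCNG2 (-0.85), GDF15 (-0.81) and MIR4680 (-0.81). Divergent transcripts differed upwards in 301 of 441 cases (adjusted p = 9.92e-29, and 7.35e-06 with an estimated correlation) and snRNAs in 36 of 39 (2.48e-46, and 0.0116 with an estimated correlation). Immediate-early genes differed downwards in 15 of 47 cases (1.31e-06, but adjusted p = 0.107 with an estimated correlation) and ISR/UPR genes in 12 of 27 (0.000289, and 0.0116 with an estimated correlation). Of the 24 genes named above by size, all 16 rises but only 2 of the 8 falls passed this test. Among the separate sets of 24 genes named by size further on, 12 of 16 rises and 7 of 8 falls did so on chromatin, and 13 of 16 rises and only 1 of 8 falls in polyA RNA. In the cytoplasm total RNA library sizes alone gave 4079 higher and 238 lower.

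On chromatin the question was whether the same RNAs build up where they are made. In DIS3-AID cells the largest rises after auxin included several genes of short structured RNAs, with counts that do not separate mature from extended forms. RNVU1-14, a variant U1 snRNA (chromosome 1, 145281116 to 145281279, plus strand), rose from 0.645 ± 0.0714 to 6.01 ± 1.34 CPM (SD, n = 3; log2 3.22 ± 0.19 SE, adjusted p = 4.65e-09), with 0.627 and 0.63 CPM in control cells. SNORD118, the U8 snoRNA that shares reads with TMEM107, rose by 3.30, AC245014.3 by 3.12 (shared with RNVU1-14), a U3 gene by 2.89, BX293535.1 by 2.71, RNVU1-19 by 2.63, RNVU1-27 by 2.41 and OSTCP1 by 2.22. Spliceosomal snRNAs rose in 23 of 34 cases (27 adjusted over the list alone; median 1.31, adjusted p = 7.43e-29, and 0.00239 with an estimated correlation), and RNU4-2 fell (-0.52). Box C/D snoRNAs rose in 43 of 143 cases (2.48e-08, but adjusted p = 0.0786 with an estimated correlation), with SNORD14B at 1.02 and SNORD35A at 0.96. Box H/ACA snoRNAs had 24 rises, such as SNORA50C (0.90) and SNORA69 (0.83), and falls of SNORA72 (-0.69), SNORA15 (-0.59) and SNORA30 (-0.36; 0.00357, but adjusted p = 0.278 with an estimated correlation). Here SNORD14B shares reads with RPS13, SNORD35A with RPL13A, SNORA50C with SNHG25 and SNORA69 with RPL39.

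Long non-coding RNAs rose less on chromatin. MIR378D2HG went from 3.18 ± 0.163 to 9.59 ± 0.667 CPM (SD, n = 3; 1.59) and CDC20-DT from 6.92 to 13.1 CPM (0.92). Divergent transcripts had 135 rises and 21 falls among 390 (159 and 29 adjusted over the list alone; median 0.29, adjusted p = 1.12e-10, and 0.00545 with an estimated correlation), antisense lncRNAs 212 and 46 among 881 (0.000242, and 0.00545 with an estimated correlation), led by MALT1-AS1 (2.14). Host genes of microRNAs rose in 18 of 44 cases (2.63e-07, and 0.0072 with an estimated correlation), including MIR222HG (521 to 740 CPM). Replication-dependent histones, which fell slightly in the cytoplasm, rose in 25 of 43 cases (30 adjusted over the list alone; median 0.41, adjusted p = 1.44e-09, but adjusted p = 0.278 with an estimated correlation), as did H2BC4 from 6.97 ± 0.449 to 10.2 ± 0.166 CPM and H3C12 (0.55). In untreated control cells histone transcripts were far lower on chromatin than in the cytoplasm (median -6.79). Their rise in this fraction therefore need not be a rise where they are made, which was not tested. Host genes of snoRNAs rose in 9 of 30 cases (9.28e-06, but adjusted p = 0.0786 with an estimated correlation), with SNHG25 at 0.78, and ribosomal protein genes in 18 of 80 (2.93e-06, but adjusted p = 0.427 with an estimated correlation), with RPL34 at 0.35. BCYRN1 (1.89) and VTRNA1-3 (1.35) led 6 rises among 10 structured Pol III RNAs (0.000436, but adjusted p = 0.0786 with an estimated correlation). Nuclear-retained lncRNAs, with LINC-PINT at 0.59 and FTX at 0.30, rose in 7 of 13 cases (0.000354, but adjusted p = 0.0786 with an estimated correlation).

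AHR targets rose on chromatin in both lines. CYP1A1, which oxidises aromatic compounds (chromosome 15, 74719542 to 74725610, minus strand), went from 0.945 ± 0.152 to 4.02 ± 0.303 CPM in DIS3-AID cells (SD, n = 3; 2.11 ± 0.14 SE, adjusted p = 7.79e-09) and from 1.02 ± 0.233 to 4.96 ± 0.0892 CPM in control cells (2.23 ± 0.13 SE, adjusted p = 4.81e-09). CYP1B1 (1.80 and 1.51), TIPARP (0.99 in DIS3-AID cells) and the hyaluronan synthase HAS3 (0.96 and 1.43) did so too. The list passed in DIS3-AID cells (6 of 7 members, adjusted p = 9.99e-16, and 0.000702 with an estimated correlation) and in control cells (6 of 7, 1.47e-20, and 0.000241 with an estimated correlation). For the difference between the lines its adjusted p was 0.911. Other protein-coding rises in DIS3-AID cells were TMEM107 (1.19), BOLA1 (0.96), CHCT1 (0.94) and CFAP161 of motile cilia (0.89). The falls were MATN4 (-1.30), the ciliary dynein DNAH5 (-1.29), SLCO2A1 (-1.12), AC004754.1 (-1.11), CCDC168 (-1.07), NIPAL2 (-1.05), SLC35G1 (-1.03) and TAF7, a TFIID subunit (21.5 ± 1.05 to 10.4 ± 1.29 CPM, -1.04), which moved from 8.82 ± 0.72 to 17 ± 1.66 CPM in control cells. ISR/UPR genes had 7 falls, with ERN1 at -0.61, and 1 rise, SLC7A11 at 0.30 (0.0431, but adjusted p = 0.427 with an estimated correlation), and p53 targets 8 falls and a rise of DDB2 (0.17; 0.0239, but adjusted p = 0.294 with an estimated correlation).

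With edgeR 5123 of 24966 genes passed on chromatin in DIS3-AID cells, 2741 higher and 2382 lower, of which 737 and 85 moved by at least 2-fold. LncRNAs had 889 rises and 263 falls among 5185, assembled loci 635 rises among 1005 (median 0.87) and protein-coding genes 914 rises and 1963 falls among 14586 (median -0.03). Library sizes alone gave 2139 higher and 3352 lower, so the balance of directions depends on the scaling.

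Chromatin RNA of control cells also differed between the untreated and the auxin group, a difference that high or low levels in either group can give. The heat shock genes moved together: HSPH1, a cochaperone of HSP70 (chromosome 13, 31134974 to 31162388, minus strand), fell from 171 ± 14.7 to 71.4 ± 4.72 CPM (SD, n = 3; -1.26 ± 0.15 SE, adjusted p = 0.000126), while DIS3-AID cells had 60.2 ± 8.79 and 64.2 ± 14.5 CPM, so the untreated control group stood above the other 3. All 9 members fell (median -0.45, adjusted p = 4.48e-16, and 0.0441 with an estimated correlation). AL353743.4 (1.84) and ASTL (1.44) rose, and LINC01068 (-1.39), ZFP2 (-1.32), RN7SL472P (-1.29) and AC145098.2 (-1.24) fell. Immediate-early genes rose in 13 of 46 cases (3.37e-05, but adjusted p = 0.968 with an estimated correlation). In all 4242 of 24966 genes passed, 2253 higher and 1989 lower, only 134 and 76 of them by 2-fold or more.

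The auxin effect in DIS3-AID minus control cells on chromatin passed in 4429 genes, 2131 higher and 2298 lower. RNVU1-14 (3.23), AC245014.3 (3.16), SNORD118 (3.12), a U3 gene (3.03) and RNVU1-27 (2.46) stood highest. ASTL (-2.03), LINC01389 (-2.0), TAF7 (-1.98), AL031289.1 (-1.85) and CFAP210 (-1.75) stood lowest. Spliceosomal snRNAs differed upwards in 20 of 34 cases (adjusted p = 3.34e-17, and 0.0271 with an estimated correlation) and divergent transcripts in 100 of 390 (1.14e-06, and 0.0362 with an estimated correlation). Histones did so in 9 of 43 cases (1.28e-06, but adjusted p = 0.397 with an estimated correlation) and heat shock genes in 8 of 9 (7.54e-10, but adjusted p = 0.0636 with an estimated correlation), and the latter rests on the same high untreated control group. Library sizes alone gave 1513 higher and 3193 lower.

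PolyA-selected cytoplasmic RNA was compared in the same way, although no library measured tails and untailed RNA can remain after selection. SNORD3A, a U3 snoRNA gene (chromosome 17, 19188016 to 19188714, plus strand), rose in DIS3-AID cells from 0.489 ± 0.117 to 9.78 ± 0.733 CPM (SD, n = 3; log2 4.30 ± 0.18 SE, adjusted p = 3.11e-16), with 0.294 and 0.295 CPM in control cells. AC245014.3 (4.72, shared with RNVU1-14), RNVU1-14 (4.52), AC103591.3 (3.56), MIR378D2HG (1.15 ± 0.349 to 10.8 ± 0.745 CPM, 3.24), AC132192.2 (2.98), MIR378D2 (2.97) and MYADM-AS1 (2.90) rose too. Divergent transcripts rose in 138 of 314 cases (164 adjusted over the list alone; median 0.60, adjusted p = 1.21e-13, and 0.00019 with an estimated correlation), ERRFI1-DT from 1.89 to 9.36 CPM. Antisense lncRNAs rose in 162 of 650 cases (1.15e-05, and 0.00458 with an estimated correlation) and snRNAs in 10 of 12 (7.77e-14, and 0.000478 with an estimated correlation). Host genes of snoRNAs rose in 15 of 28 cases (2.26e-07, and 0.0469 with an estimated correlation), with SNHG3 from 67.9 to 137 CPM, and nuclear-retained lncRNAs in 6 of 13 (1.15e-05, and 0.0199 with an estimated correlation), NEAT1 going from 35.6 ± 1.03 to 69.9 ± 5.65 CPM. LINC genes rose in 60 of 278 cases (0.00437, but adjusted p = 0.0747 with an estimated correlation) and H/ACA snoRNAs in 17 of 48 (0.000276, and 0.0174 with an estimated correlation).

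Immediate-early genes were lower in this set as well, although values of protein-coding genes here appear to cover their non-coding models only. NR4A1 went from 186 ± 11.9 to 108 ± 15.6 CPM (SD, n = 3; -0.78 ± 0.14 SE), with 431 and 367 CPM in control cells, and DUSP6 from 64 to 42.3 CPM. The list had 10 falls among 24 (12 adjusted over the list alone; median -0.37, adjusted p = 2.26e-07, and 0.0174 with an estimated correlation). ISR/UPR genes (5 of 15 fell; 0.00108, and 0.0231 with an estimated correlation) and p53 targets (7 of 26 fell; 0.00217, and 0.0447 with an estimated correlation) followed, with CALR at -0.41 and CDKN1A at -0.35. The largest falls were the calcium pump ATP2B4 (-1.15), LGI3 (-0.92), GDF15 (16.6 ± 3.87 to 9.3 ± 0.659 CPM, -0.83), MR1 (-0.79), MIR4260 (-0.79, shared with LAMB3), THBS1 (-0.78) and PRODH (-0.77). Protein-coding rises were FAM174B (2.68), LEKR1 (1.68), the cytolinker PLEC (1.64), ZNF48 (1.36), PSCA (1.21), NEMP1 (1.18), WNT10A (1.14) and NAALADL2 (1.07).

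In the polyA set 2861 of 16651 features passed, eRNA regions and assembled loci included, 2157 higher and 704 lower, with 1557 and 8 of at least 2-fold. Regions named as enhancer RNA, short transcripts made at enhancers, rose in 732 of 1462 cases (median 0.77), assembled loci in 489 of 783 (median 1.44) and lncRNAs in 639 of 2793. Protein-coding genes had 161 rises and 670 falls among 10086 and a median of -0.06 that became 0.00 with library sizes alone, and the files appear to hold only their non-coding models. Library sizes alone gave 2342 higher and 335 lower.

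Auxin in control cells passed in 8 of 16651 genes of the polyA set (865 at unadjusted p < 0.05; 27 with DESeq2). NABP1, a single-strand DNA binding protein, fell from 14.9 ± 1.15 to 7.12 ± 0.993 CPM (SD, n = 3; -1.07 ± 0.11 SE, adjusted p = 3.59e-06). CLK1 (-0.54), CREBZF (-0.47), VCL (-0.47), ARMC7 (-0.42) and BDNF (-0.32) fell and DEPP1 (0.75) and TSC22D1 (0.39) rose. The difference between the lines passed in 974 genes, 793 higher and 181 lower. Its highest members were AC245014.3 (4.73), RNVU1-14 (4.40), SNORD3A (4.29), AC103591.3 (3.92) and FAM174B (2.94), and its lowest DEPP1 (-1.41), FBXL8 (-1.16), RGMA (-1.16), LGI3 (-1.12) and ANG (-0.92). Divergent transcripts differed upwards in 44 of 314 cases (adjusted p = 3.04e-15, and 8.9e-05 with an estimated correlation) and immediate-early genes downwards in 6 of 24 (4.82e-09, and 0.00867 with an estimated correlation). Library sizes alone gave 856 higher and 73 lower for this difference.

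**Figure D3:**
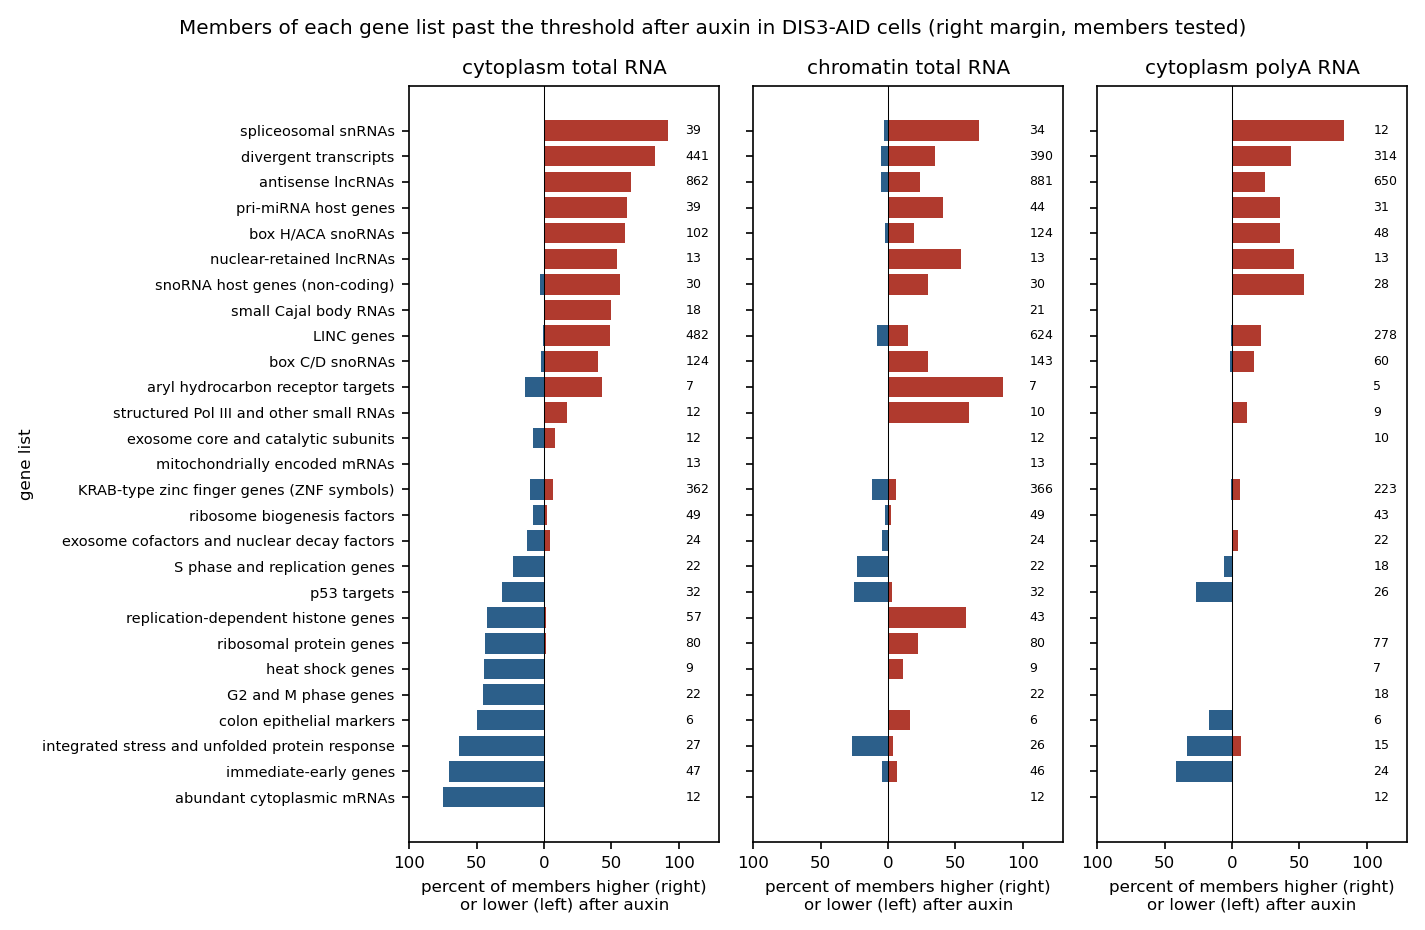
Percent of the tested members of each gene list that were higher or lower after auxin in DIS3-AID cells, in the 3 data sets. The number of tested members stands in the right margin.

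Before any auxin the clone already differed from the control line. TNFSF4, a cytokine of the TNF family, was at 1.48 ± 0.0748 CPM in control and 29.8 ± 1.49 CPM in DIS3-AID cytoplasm (SD, n = 3; log2 4.33 ± 0.10 SE, adjusted p = 8.72e-15), and LRP1B (3.94), the matrix protein SPARC (3.21) and MT-TI (2.43) were higher as well. NRIP1, a nuclear receptor corepressor, was nearly absent from the clone, with 1260 against 2 counts (ratio 514, 95% interval 142 to 4250), and AZGP1P2 nearly absent from the control line, with 2 against 600 counts (368, 101 to 3040). AF127577.4, which shares reads with NRIP1, stood at -7.88, ZNF850 at -3.78, EGR2 at -2.27 and FOSB at -2.05 (194 ± 42 against 47 ± 22.9 CPM). Immediate-early genes were lower in 30 of 47 cases and MYC higher (0.28; median -0.45, adjusted p = 1.26e-23, and 0.0273 with an estimated correlation). Lower too were 19 of 32 p53 targets (1.53e-08, and 0.0294 with an estimated correlation) and 7 of 27 ISR/UPR genes (0.0043, and 0.0447 with an estimated correlation).

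Mitochondrially encoded mRNAs were higher in 12 of 13 cases (median 1.89, adjusted p = 1.53e-08, but adjusted p = 0.198 with an estimated correlation), and mitochondrial transcripts made up 0.633 ± 0.15% of cytoplasmic counts in control and 2.41 ± 0.73% in DIS3-AID cells (SD, n = 3; exact p = 0.1). Some non-coding lists were higher in the cytoplasm before auxin, which did not hold in every data set: snoRNAs on chromatin had 6 members higher and 66 lower of 346 (median -0.13), and polyA lncRNAs 94 higher and 109 lower. In the cytoplasm total RNA antisense lncRNAs had 88 members higher and 48 lower (0.0285, and 0.0294 with an estimated correlation, 0.0550 with library sizes alone), pri-miRNA hosts 12 higher and MIR600HG (-0.51) and MIR4697HG (-0.36) lower (0.000443, and 0.0273 with an estimated correlation). Box C/D snoRNAs had 35 higher and SNORD3A (-0.94) and SNORD104 (-0.69) lower (1.28e-06, but adjusted p = 0.0678 with an estimated correlation), H/ACA snoRNAs 21 higher and SNORA70 (-0.61) lower (7.82e-06, but adjusted p = 0.0517 with an estimated correlation). In the cytoplasm 5085 genes passed, 2227 higher and 2858 lower, or 2743 and 2209 with RLE scaling. With 1 clone of each kind, these differences include any other difference between the clones.

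The same comparison passed in 8120 genes on chromatin, 3785 higher and 4335 lower, and 4788 higher and 3359 lower with library sizes alone. AZGP1P2 (8.75), CARMAL (4.04), TNFSF4 (3.61), LINC02058 (3.11) and SPARC (2.67) stood highest and NRIP1 (-7.78), AF127577.4 (-4.20), ZNF850 (-3.62), ERBB4 (-3.34) and TUSC3 (-2.55) lowest. Heat shock genes were lower in 9 of 9 cases (median -0.66, adjusted p = 5.08e-11, but adjusted p = 0.219 with an estimated correlation), against the same untreated control libraries in which HSPH1 stood above all other groups, and immediate-early genes in 28 of 46 (5.34e-10, but adjusted p = 0.444 with an estimated correlation). In polyA RNA 2009 genes passed, 922 higher and 1087 lower. TNFSF4 (4.88), SPARC (3.08), SLCO4A1-AS1 (2.83) and MT-TF (2.66) were higher, VIM-AS1 (-2.78), EGR2 (-2.19), FOSB (-1.84) and GGT1 (-1.84) lower. For AZGP1P2 the polyA counts were 1 against 148 (ratio 164, 29 to 6520) and for AF127577.4 214 against 1 (193, 34.3 to 7670). Immediate-early genes were lower in 14 of 24 cases (7.21e-18, and 0.00591 with an estimated correlation) and p53 targets in 10 of 26 (6.57e-08, and 0.0102 with an estimated correlation). Protein-coding values in polyA RNA again appear to cover non-coding models only.

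Fractions were compared in untreated control cells to place these RNAs. Of 1433 assembled loci 1018 were lower and 215 higher on chromatin than in the cytoplasm. LncRNAs went the other way, with 3638 higher and 1398 lower of 5902. All 1433 loci passed the expression filter in the cytoplasm total RNA, against 1005 on chromatin and 783 in polyA RNA. If the loci were assembled from the cytoplasm libraries, their placement there is not independent evidence. Histone transcripts lay in the cytoplasm: all 56 tested were lower on chromatin (median -6.79, or -6.74 with genes near 0 counts at their bound), as were 79 of 80 ribosomal protein genes (-4.61), all 47 immediate-early genes (-3.82) and all 12 abundant mRNAs (-5.11). RPPH1, the RNA of RNase P (chromosome 14, 20343075 to 20343407, minus strand), stood at -10.0 with AL355075.4 at -9.99 on the same reads, followed by AL591846.1 (-8.94), AP001324.1 (-8.89) and RPS2P55 with 1036 against 2 counts (ratio 801, 221 to 6630). Highest on chromatin were AC245060.5 (7.38), AC010997.5 (6.12), AC023421.2 (5.58), FLJ42393 (5.57) and AL390318.1 (5.52). Box C/D snoRNAs were higher there in 121 of 146 cases (2.27, or 2.23 at the bound) and H/ACA snoRNAs in 114 of 127 (1.89), where SNORA59A, SNORA70 and SNORA50C were lower. Retained lncRNAs had 10 of 13 higher (3.35) and OIP5-AS1 (-2.38), TUG1 (-1.61) and HOTAIRM1 (-1.08) lower. In total 24731 of 27418 genes passed (12665 higher, 12066 lower), and the protein-coding median of -0.54 turned to 0.12 with library sizes alone, which moved the median of all features from 0.096 to 0.755.

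Set against each other, the 2 responses of DIS3-AID cells to auxin differed as log2 ratios, which also depend on how low a transcript starts in each fraction. The lncRNA share of counts went up by a similar amount in both without passing, from 4.63 to 5.26% in the cytoplasm and from 6.97 to 7.54% on chromatin (n = 3, exact p = 0.1 each). LINC02989 (-4.14), SKAP1-AS1 (-3.78), AC097716.1 (-3.57), SEC61G-DT (-3.43) and AC078980.1 (-3.37) had the largest deficits on chromatin. Divergent transcripts responded less there in 257 of 460 cases (median -1.04) and ICMT-DT (0.81), MTA1-DT (0.95), BAIAP2-DT (0.59) and CTBP1-DT (0.66) more. Antisense lncRNAs responded less in 404 of 989 cases (-0.62), LINC genes in 205 of 713 and H/ACA snoRNAs in 49 of 127. Histones went the other way in 32 of 56 cases (0.51), with H2BC6 at -0.94, as did 48 of 80 ribosomal protein genes (0.26) and 6 of 7 AHR targets (0.63). H3P16 (1.68), CYP1B1 (1.37), GPANK1 (1.32), CISD3 (1.32) and PPIAP22 (1.26) were highest. Of 27418 genes 5305 passed, 1224 higher and 4081 lower on chromatin, or 379 and 5514 with library sizes alone, which moved the median of all features from -0.048 to -0.169.

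Few genes set the polyA response in the cytoplasm apart from the total RNA response. AC090023.2 (-3.02), SNORD95 (-2.84) and MYL12-AS1 (-2.79) had lower responses in polyA RNA, and SCARNA2 (3.40), AL356488.2 (3.39), RNVU1-19 (3.23) and SNORD3A (2.85) higher ones. The values of CFAP57 (-5.48), MYO16 (-2.72) and SRGAP2B (2.54), which are protein-coding, appear to compare different transcript models of the gene and are no measure of a polyA response. AL356488.2 shares reads with SCARNA2. Divergent transcripts responded less in 67 of 429 cases (median -0.49), antisense lncRNAs in 125 of 824, with only ZNF436-AS1 responding more (1.84), and LINC genes in 51 of 432. Box C/D snoRNAs split, with SNORD12B (3.66) and SNORD3A higher and SNORD45A (-2.66), SNORD43 (-2.14), SNORD89 (-1.73), SNORD118 (-1.54) and SNORD95 lower. In all 754 of 18669 genes passed, 78 higher and 676 lower, and 983 with the replicate number as a block.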

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

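The scaling test of the cytoplasm rise, the percents of genes with a control group highest or lowest, and all counts of other splits of the libraries were chosen after the results they test had been seen, while the other tests had been written down with their limits beforehand. Differences between 2 responses come first, as values.

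Between the lines, the auxin effect differed in 4459 genes of the cytoplasm total RNA, 4429 of the chromatin and 974 of the polyA RNA. In the cytoplasm total RNA the largest differences were SKAP1-AS1 4.49, AL390961.3 4.40, SELENOOLP 4.33, ZBTB20-AS5 4.30, AC005808.1 3.93, RPL17P6 -0.90, SPARC -0.86, CCNG2 -0.85, GDF15 -0.81 and MIR4680 -0.81. On chromatin they were RNVU1-14 3.23, AC245014.3 3.16, SNORD118 3.12, U3 3.03, RNVU1-27 2.46, ASTL -2.03, LINC01389 -2.00, TAF7 -1.98, AL031289.1 -1.85 and CFAP210 -1.75. In polyA RNA they were AC245014.3 4.73, RNVU1-14 4.40, SNORD3A 4.29, AC103591.3 3.92, FAM174B 2.94, DEPP1 -1.41, FBXL8 -1.16, RGMA -1.16, LGI3 -1.12 and ANG -0.92. The response of DIS3-AID cells differed between chromatin and cytoplasm in 5305 genes, with H3P16 1.68, CYP1B1 1.37, GPANK1 1.32, CISD3 1.32, PPIAP22 1.26, LINC02989 -4.14, SKAP1-AS1 -3.78, AC097716.1 -3.57, SEC61G-DT -3.43 and AC078980.1 -3.37. It differed between polyA and total RNA in 754 genes, with SCARNA2 3.40, AL356488.2 3.39, RNVU1-19 3.23, SNORD3A 2.85, SRGAP2B 2.54, CFAP57 -5.48, AC090023.2 -3.02, SNORD95 -2.84, MYL12-AS1 -2.79 and MYO16 -2.72. Of these, CFAP57, MYO16 and SRGAP2B are protein-coding and appear to be counted on different transcript models in the 2 sets.

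Assembled loci and lncRNAs rose in the cytoplasm of DIS3-AID cells after auxin, and nuclear RNA carried into that fraction could look the same. The test used 224 chromatin-enriched genes that auxin left alone on chromatin. Their limits, set with the test, were log2 at least 3, at least 5 CPM there, adjusted p of at least 0.5 and a change under 0.1. Their gain in the cytoplasm after auxin was taken as a percent of their chromatin level (median 0.65%). That percent would give a median of 0.37% of the rise of 3286 features (quartiles 0.12 and 1.5%). Its upper quartile would give 1.11%, where 50% or more had been set as the mark of that cause. The result argues only against added carry-over of chromatin RNA after auxin. A constant carry-over of RNAs that rose on chromatin was not computed and stays open. Soluble nuclear RNA was not sequenced, so its carry-over could not be tested and stays open. In untreated control cells 1018 of 1433 assembled loci were lower on chromatin than in the cytoplasm, which keeps their predicted carry-over small. That placement is not independent evidence if the loci were assembled from the cytoplasm libraries. Composition scaling is also argued against: the lower of the loci's medians with RLE factors and with library sizes alone was 2.62. For lncRNAs, reads of overlapping annotated genes on the same strand are argued against too. The 2803 without such an overlap had a median of 0.85 and the 1627 with one had 0.22 (95% interval of the difference 0.56 to 0.69). Assembled loci have no coordinates, so their overlaps, also with lncRNAs, could not be tested. Whether the nuclear envelope or the transcripts' own export changed stays open, as no library measured it.

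Chromatin RNA of control cells differed between the untreated and the auxin group in 4242 genes, and untreated control libraries that stand apart are a candidate explanation. Only 53.6% of these genes moved the same way in DIS3-AID cells, below the 60% set beforehand for that explanation, though a response confined to control cells would give the same. Among the genes past the threshold the untreated control group was the highest or lowest of the 4 group means in 75.4% and the auxin-treated control group in 51.4% (52.1 and 42.0% among the other genes). Auxin acting on chromatin RNA in both lines cannot be told from this: genes past the threshold in both lines and in 1 direction were 1.69 times the number independent lists would share, between the set limits of 1.2 and 2. There were 345 genes higher in both against 247.4 and 392 lower in both against 189.8, but 524 past in opposite directions, and the responses had a Spearman rho of 0.04 over all genes.

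Assembled loci were already higher in the cytoplasm of untreated DIS3-AID cells (median 0.28), and a partial loss of DIS3 without auxin could cause that. Across 1005 loci the untreated difference in the cytoplasm and the auxin response on chromatin, which share no libraries, had a Spearman rho of 0.31 (95% interval over loci 0.25 to 0.37), so the test cannot tell, the interval reaching below the 0.3 set beforehand. The 635 loci higher on chromatin after auxin had a median untreated difference of 0.35 and the 370 others 0.11. Composition scaling is argued against, with a lower median of 0.30 under RLE factors and library sizes alone. A difference between the clones apart from the degron stays open.

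Regrouping the libraries gave too few splits for a verdict in the comparisons of 2 groups, where the labelled split was 1 of 10 and every other gave 0 genes. This holds for auxin in DIS3-AID cells (7894 genes in the cytoplasm total RNA, 5123 on chromatin, 2861 in polyA RNA), auxin in control cells (11, 4242 and 8), DIS3-AID against control cells (5085, 8120 and 2009) and chromatin against cytoplasm (24731). For the auxin effect between the lines, 1 of 100 splits reached the count on chromatin (highest other 1434), 6 of 100 in the cytoplasm total RNA (highest other 5888) and 6 of 100 in polyA RNA (highest other 1457). In both sets all 6 kept the DIS3-AID libraries as they are, as 8 of the splits drawn did, so the response of those cells could set the count there. For chromatin minus cytoplasm 1 of 100 splits reached 5305 (highest other 4754). The split with 4754 kept the cytoplasm labels and changed those of chromatin, which by construction leaves the cytoplasm response in the difference. With both changed the highest was 471, so the cytoplasm response alone could set much of the count. For polyA minus total RNA 10 of 100 reached 754 and the highest other gave 3931, several times the real count. That split kept the labels of the cytoplasm total RNA, as did 9 of the 10, and changed those of the polyA RNA, which by construction leaves the total RNA response in the difference.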

How the results depend on the processing

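The alternatives added after the first results had been seen are the 2 that leave out assembled loci and eRNA regions or overlapping features. Scaling moved the balance of directions as well as counts. Counts moved by over 1.5 times as follows, and the cause was not tested unless it is given.

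The test against a 1.5-fold change asks for more by construction. It gave 3377 genes for auxin in DIS3-AID cells in the cytoplasm total RNA, 456 on chromatin and 1354 in polyA RNA, and 1, 41 and 0 for auxin in control cells. For DIS3-AID against control cells it gave 235, 379 and 109, for the auxin effect between the lines 2632, 271 and 388, for chromatin minus cytoplasm 2099 and for polyA minus total RNA 219.

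Auxin in control cytoplasm, 11 genes, gave 62 with the replicate block, 75 with DESeq2, 245 without the filter, 5 without loci, 5 without overlapping features, 4 with RLE factors, 5 without small RNAs and 4 with min.count 50. In control polyA RNA, 8 genes, it gave 22 with the block, although the pairing rule was not met there, 27 with DESeq2 and 36 without the filter. Auxin in DIS3-AID polyA RNA gave 1262 without loci and eRNA regions and 1313 with min.count 50, where the features themselves are left out, and the effect between the lines there 349 and 625. Library sizes alone moved the balance of directions where the report gives its counts, and reversed COL1A1 between fractions (0.17, from -0.49).

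With 1 library left out the counts ranged as follows. Auxin in control cells gave 1 to 34 in the cytoplasm, 2313 to 4704 on chromatin and 4 to 28 in polyA RNA. In the cytoplasm the values were 4, 4 and 34 without auxin replicates 1, 2 and 3 and 3, 1 and 3 without untreated replicates 1, 2 and 3. On chromatin they were 2597 without auxin replicate 1 and 2313 without untreated replicate 3, and in polyA RNA 4, 5 and 28 without auxin replicates 1, 2 and 3 and 4 without untreated replicate 2 or 3. DIS3-AID against control cells in polyA RNA gave 1206 to 2203, with 1303 without DIS3-AID untreated replicate 1 and 1206 without control untreated replicate 2. Other ranges were 6106 to 7113, 3613 to 4806 and 2501 to 2825 for auxin in DIS3-AID cells, 3441 to 4764 and 5705 to 8498 for DIS3-AID against control cells in the cytoplasm and on chromatin, 3866 to 4623, 3080 to 4951 and 706 to 985 for the effect between the lines, 24449 to 24827 between fractions, 4639 to 5152 for chromatin minus cytoplasm and 577 to 826 for polyA minus total RNA.

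Of 140 list calls, 49 were kept with an estimated correlation, 118 with fry, 124 with library sizes alone and 134 with the block. Deviations of libraries with the same number had r from -0.522 to 0.426 in the other comparisons, short of the rule for a block.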

Other observations

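The overlaps given here were counted after the results they compare had been seen. Features that rose after auxin in DIS3-AID cells, assembled loci included, were shared between data sets more often than independent lists would be. The direction of the loci is not independent evidence if they were assembled from these libraries. The libraries differ, but cytoplasm total and polyA libraries with the same number shared deviations (r from 0.315 to 0.538), so these 2 sets appear to come from the same samples and are not independent. Among features tested in both, 1566 rose in the cytoplasm total RNA and on chromatin, against 516.6 for independent lists, and 1310 in the total and polyA RNA of the cytoplasm, against 255.7, which is 92.4% of the polyA rises. For falls the shared numbers were 462 between the compartments, against 323.2, and 538 within the cytoplasm, against 106.8. LINC-PINT, NEAT1 and the divergent transcript ERRFI1-DT were among the lncRNAs that rose in both cytoplasm sets, and NR4A1, GDF15, DUSP6 and CDKN1A among the falls there. PolyA falls of protein-coding genes appear to be counted on their non-coding models only.

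Zinc finger and ribosome genes differed between the untreated lines in the cytoplasm, with calls that were each lost with an estimated correlation. On chromatin the medians were 0.01 for the ZNF-symbol list and 0.03 for ribosome biogenesis factors. Genes of the ZNF-symbol list were lower in 91 and higher in 12 of 362 cases in DIS3-AID cytoplasm (camera adjusted p = 1.43e-05, but adjusted p = 0.16 with an estimated correlation), and ribosome biogenesis factors higher in 18 of 49 (5.82e-05, but adjusted p = 0.198 with an estimated correlation). The markers KRT18 (0.41), KRT8 (0.29) and CDH1 (0.22) of the colon epithelium were higher as well. In polyA RNA the biogenesis factors were higher in 15 of 43 cases (6.57e-08, but adjusted p = 0.176 with an estimated correlation), and ribosomal protein genes lower in 10 of 77 (1.96e-05, but adjusted p = 0.754 with an estimated correlation). On chromatin G2/M genes were higher in 12 and lower in 2 of 22 cases (0.0234, but adjusted p = 0.663 with an estimated correlation).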
